A study of Mus musculus with 15 samples.

How the data were processed

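RNA from 15 cultures of one mouse melanocyte line was hybridised to one-colour Affymetrix arrays after biotin labelling, per the labels' protocols. Cells were grown at 37 °C in medium with 10% serum, 200 nM phorbol ester and 200 pM cholera toxin, and hypoxia was 1% oxygen, 5% CO2 and 94% nitrogen for 24 h, per the labels' protocols. The authors deposited one table of log2 intensities for all arrays, with 41345 probe sets. RMA (which corrects background, quantile-normalizes and summarises probes) and Partek are named in the submitters' processing notes without version, settings or order. Filters and batch handling are not given in the sources used here. The values ran from 2.6 to 14.9 with near-equal medians, as log2 summaries normalized between arrays have. Quantile normalization forces the arrays to nearly the same distribution, so a change of all genes together could not be seen, and fold changes of dim genes are compressed toward 0. The file has no detection calls, so no gene was called absent.

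Groups were taken from the sample labels, 3 arrays in each of 5 groups. No array's columns were shared, doubled or unmatched. Probe sets were named through the platform annotation. Of 41345, 23521 had exactly 1 gene symbol, 1814 had several and 16010 had none in that table, and only those with 1 were used. Entrez identifiers of 23328 of them were found in the RefSeq table (assembly GRCm38.p6), which changed 0 symbols, and 193 were not found and kept their annotated symbol. No coordinates are given because the files name no genome build. For the 1082 genes with more than 1 probe set, the probe set with the highest mean over all arrays stood for the gene, which left 22180 genes. Probe sets of a gene can disagree, and the second probe sets of Hif1a, Pdk1, Plekha2, Car9, Pole, Slc7a11, Rrm2 and Ddx21 are given in the text.

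From the deposited log2 values, limma 3.58.1 in R 4.3.3 fitted 5 group means to all 15 arrays, with eBayes moderation and no covariates. One fit over all groups shares one estimate of each gene's spread. Contrasts were the hypoxia control against normoxia, the negative control against the hypoxia control, each siRNA and their mean against the negative control, and Si1 against Si6. Tests were two-sided with Benjamini-Hochberg adjustment over all genes of a comparison and a threshold of 0.05. Counts of large changes added a log2 fold change of at least 1. The median standard error of a log2 fold change between 2 groups was 0.076. In simulated data with the real genes' means and spreads, 67, 67 and 66 genes were changed by 0.5, 1 and 2 on the log2 scale. The hypoxia contrast recovered 94% of those changed by 0.5 and 100% of those changed by 1 or 2, and called 0.036% of unchanged genes. Far more genes passed the real tests, and the cutoff loosens as more pass, so the real share of unchanged genes called can be higher.

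Before the data were examined, 16 gene lists and 5 lists of markers of other cell types were fixed, 374 genes in all, of which 341 were measured. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01 and again with the correlation estimated from the residuals, adjusted over the 16 lists within a comparison. Counts of changed members are given over all genes tested and adjusted over the list alone. The named genes follow a rule also fixed before the data were examined. It takes Hif1a, the 10 largest rises and 10 largest falls of each comparison among genes past the test whose arrays do not overlap between the groups, up to 4 members with the largest change from each list, and the 15 genes with the largest hypoxia change in each overlap of hypoxia and both siRNAs. Genes without an established symbol could be left unnamed. Second probe sets of named genes and the gene families of the closing section are outside this rule.

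Alternatives were another quantile normalization, median centring, leaving out the lowest 25% or 50% of genes by mean level, the mean of a gene's probe sets, eBayes with trend and robust settings, no variance moderation, array weights, only the compared groups in the fit, the replicate letter as a block, the negative control in place of the hypoxia control, and leaving out each array in turn. The tests of the closing section that chose and tested genes on one group's arrays were also run with that group's arrays parted, 6 ways each. Changes were also set against the 200 genes nearest in mean level. These tests took the place of ones written before the data were tested, whose outcome array centring or shared arrays partly fix. Normalization between arrays partly fixes the outcome of the level-matched tests too. For comparisons that share the negative control arrays, 50 simulations of unchanged groups gave the values expected without any effect. All 15 arrays were used. Scanner files and protein measurements were not analysed here.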

Results

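Gene expression was measured on 15 one-colour Affymetrix arrays from melan-Ink4a-Arf-1, an immortal line of pigment cells (melanocytes) from mice that lack the Cdkn2a tumour suppressor locus. The arrays fell into 5 groups of 3, described in the series as biological triplicates. Normoxic cells grew at about 21% oxygen and 10% CO2. The other 4 groups spent 24 h at 1% oxygen and 5% CO2, so oxygen and CO2 changed together and their effects cannot be separated. Of the hypoxic groups, one was labelled control (here the hypoxia control) and one negative control, with no further account of what either received. The remaining pair, Si1 and Si6, was transfected 24 h before hypoxia with one of 2 small interfering RNAs (siRNAs) against Hif1a. Hif1a encodes the oxygen-regulated subunit of hypoxia-inducible factor 1, a transcription factor that is stabilised when oxygen is low. The comparisons address which genes respond to low oxygen in melanocytes and which of these responses need Hif1a. The median of each array's deposited log2 values lay between 6.52 and 6.61. Pairs of arrays from the same group correlated at 0.9931 to 0.9957 across all 41345 probe sets, and pairs from different groups at 0.9782 to 0.9931. A ± after a log2 fold change is limma's standard error with 3 arrays per group, and all adjusted p-values are limma's or camera's after Benjamini-Hochberg adjustment. With 3 arrays per group, their number limits the precision.

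Hif1a mRNA, the siRNA target, was lowest in the siRNA groups. Its level was 10.34 ± 0.03 log2 units (SD, n = 3) in normoxia, 10.59 ± 0.05 in the hypoxia control, 10.63 ± 0.06 in the negative control, 8.65 ± 0.09 in Si1 and 8.93 ± 0.04 in Si6. Against the negative control the log2 fold change was -1.98 ± 0.06 in Si1 (limma adjusted p = 1.7e-12) and -1.7 ± 0.06 in Si6 (limma adjusted p = 1.8e-11), which left 25.3% and 30.7% of the negative control level. The difference between the siRNAs, -0.28 ± 0.06 for Si1 against Si6, passed the test (adjusted p = 0.001). Hypoxia raised Hif1a mRNA by 0.25 ± 0.06 (adjusted p = 0.004), and the negative control did not differ detectably from the hypoxia control (0.05 ± 0.06, adjusted p = 0.694). These values are from the brighter of the 2 Hif1a probe sets (17276328). The dimmer one, at a mean of 5.40, did not follow the knockdown, with -0.01 in Si1 and -0.07 in Si6 (adjusted p = 0.956 and 0.538). With the mean of both probe sets the hypoxia rise no longer passed the test, at 0.12 (adjusted p = 0.134), nor did the difference between the siRNAs, at -0.11 (adjusted p = 0.173). Over all 16 alternatives the limma adjusted p ran from 4.7e-04 to 0.134 for the rise and from 8.7e-05 to 0.173 for the difference.

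**Figure D1:**
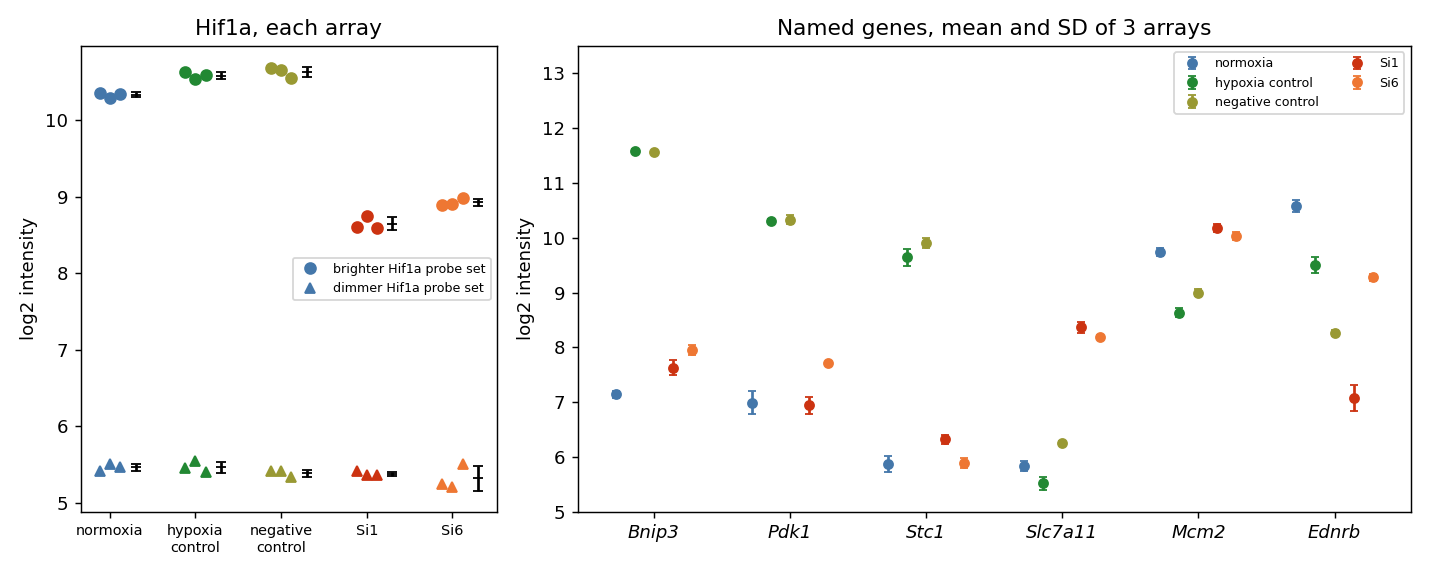
Log2 intensity of the brighter and the dimmer Hif1a probe set on each of the 15 arrays, with the mean and SD of 3 arrays as black bars (left), and mean and SD of 3 arrays for 6 named genes in the 5 groups (right). The brighter Hif1a probe set is at 8.65 in Si1 and 8.93 in Si6 against 10.63 in the negative control, and the dimmer one averages 5.40.

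Low oxygen raised most measured genes of the fixed glycolysis and hypoxia adaptation lists, among them Pdk1, Bnip3, Fam162a and Car9. Of all genes, the largest rise was in Prelid2 (4.91 ± 0.10, adjusted p = 8.9e-14), followed by the mitophagy receptor Bnip3 (4.44 ± 0.07, adjusted p = 3.1e-15) and the secreted glycoprotein Stc1 (3.77 ± 0.09, adjusted p = 2.8e-13). Pdk1, a kinase that inactivates pyruvate dehydrogenase, rose by 3.32 ± 0.09, Fam162a by 3.29 ± 0.09, the lipoprotein receptor Vldlr by 3.21 ± 0.09, Plekha2 by 2.93 ± 0.08, the carbonic anhydrase Car9 by 2.92 ± 0.11 and Clybl by 2.69 ± 0.07. Among the genes that fell were the mitochondrial carrier Slc25a35 (-1.65 ± 0.07), Parp8 (-1.47 ± 0.13), the lipid transporter Abca12 (-1.46 ± 0.08), Cpt1a, which admits long-chain fatty acids to mitochondria (-1.29 ± 0.05), Mob3b (-1.24 ± 0.08) and Castor2 (-1.22 ± 0.09). In all, 4664 of 22180 genes passed the test between the hypoxia control and normoxia, 2190 higher and 2474 lower. The share of higher genes among them was 47% as deposited, 52.2% after quantile normalization and 50% after median centring, so the majority direction depends on the scaling. At least 2-fold changes were mostly rises, with 128 genes up and 30 down. For Pdk1, Plekha2 and Car9, a second probe set did not show the rise, at 0.09, 0.05 and 0.25. By the mean over all arrays these were dimmer, at 3.45, 6.72 and 7.33 against 8.45, 8.15 and 7.8 for the chosen ones. The rise itself lifts that mean in the chosen probe sets, so level does not settle the disagreement for Plekha2 and Car9.

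The gene lists fixed before the data were examined moved in distinct directions with hypoxia. In the glycolysis and glucose uptake list, 17 of 21 measured genes rose and 0 fell (18 rose adjusted over the list alone), with a median of 1.23. Its largest changes after Pdk1 were in hexokinase Hk2 (2.64 ± 0.07), glycogen synthase Gys1 (1.81 ± 0.06) and the lactate exporter Slc16a3 (1.77 ± 0.10). Of 25 genes of HIF feedback and hypoxia adaptation, 24 rose and 1 fell (24 and 1 adjusted over the list alone), with a median of 1.01 and Higd1a (2.51 ± 0.08) among the largest after Bnip3, Fam162a and Car9. Among 16 secreted and angiogenic factors 8 rose and 1 fell (8 and 1 adjusted over the list alone), among them Adm (2.63 ± 0.11), Vegfa (2.17 ± 0.05) and Cxcl12 (1.05 ± 0.08). The camera adjusted p was 1.1e-27 for glycolysis, 1.4e-38 for hypoxia adaptation and 5.4e-08 for secreted factors, and these 3 calls held with an estimated correlation. Of 13 JmjC histone demethylases, oxygen-dependent enzymes, 8 rose and 1 fell (8 and 1 adjusted over the list alone), led by Kdm4b (1.19 ± 0.06) and Kdm3a (1.12 ± 0.06). That list's camera adjusted p was 5.3e-05, and its call was lost with an estimated correlation (adjusted p = 0.072).

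DNA replication genes fell together in the hypoxia control against normoxia. Of 25 measured, 24 fell and 0 rose (24 adjusted over the list alone), with a median of -0.61, and the call held with an estimated correlation (camera adjusted p = 3.4e-22 and 0.004). In the negative control, also hypoxic, the list lay above the hypoxia control by a median of 0.48, so the fall was not shared in full by both hypoxic controls. In the hypoxia control the helicase subunit Mcm2 fell by 1.12, the chromatin assembly factor Chaf1b by 1.07, the polymerase Pole by 0.98 and Mcm3 by 0.95 on the log2 scale. A second, dimmer probe set of Pole did not show the fall, at 0.04. The mitosis list did not fall with it, as 7 of 20 genes rose and 0 fell (11 and 1 adjusted over the list alone), with Cenpf at 0.54 ± 0.06 and Cenpe at 0.51 ± 0.07. The mitosis call (camera adjusted p = 7.5e-04) was lost with an estimated correlation (adjusted p = 0.309). In the melanocyte lineage and pigmentation list 14 of 23 genes fell and 1 rose (16 and 1 adjusted over the list alone), with a median of -0.27 and camera adjusted p = 1.7e-08, or 0.035 with an estimated correlation. The endothelin receptor Ednrb fell by 1.08, Gpr143 by 1.0, the melanosome transporter Slc45a2 by 0.89 and Rab27a, which moves melanosomes, by 0.72.

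Smaller falls were seen in several biosynthetic lists, all called with the preset correlation and none with an estimated one. Of 15 cholesterol synthesis genes 8 fell and 0 rose (9 adjusted over the list alone; camera adjusted p = 1.8e-05, and adjusted p = 0.072 with an estimated correlation), with Msmo1 at -0.57 ± 0.05. Of 20 genes of the integrated stress response and amino acid supply 11 fell and 2 rose (12 and 2 adjusted over the list alone; camera adjusted p = 1.6e-04, and adjusted p = 0.083 with an estimated correlation), with the serine enzyme Shmt2 at -0.76 ± 0.07 and the amino acid transporter Slc7a5 at -0.73 ± 0.06. Of 19 ribosome biogenesis genes 10 fell and 2 rose (13 and 3 adjusted over the list alone; camera adjusted p = 0.001, and adjusted p = 0.083 with an estimated correlation). Of 18 ER chaperone genes 8 fell and 1 rose (9 and 1 adjusted over the list alone; camera adjusted p = 8.4e-04, and adjusted p = 0.072 with an estimated correlation), and of 14 citrate cycle genes 5 fell and 0 rose (5 adjusted over the list alone; camera adjusted p = 0.002, and adjusted p = 0.175 with an estimated correlation). Respiratory chain subunits were not called (median -0.05, camera adjusted p = 0.051), with 4 of 30 lower, nor were the HIF subunits and regulators (0.746), p53 targets (0.134) and the interferon response (0.28).

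The negative control differed from the hypoxia control although both were hypoxic. Genes of cell division were higher and pigment cell genes lower in the negative control. All 20 mitosis genes rose (20 adjusted over the list alone), with a median of 0.71, the motor proteins Kif11 at 0.94 ± 0.06 and Kif23 at 0.93 ± 0.07, and camera adjusted p = 5.0e-32. Of 25 DNA replication genes 18 rose and 0 fell (19 adjusted over the list alone; camera adjusted p = 5.8e-19), led by Mcm4 (0.80 ± 0.05), Pole (0.79 ± 0.06) and Pola1 (0.78 ± 0.06), though a second, dimmer probe set of Pole was at -0.14 (adjusted p = 0.18). Of 23 pigmentation genes 20 fell and 0 rose (21 adjusted over the list alone; camera adjusted p = 1.8e-23), with Rab27a at -1.28 ± 0.08, Ednrb at -1.24 ± 0.10, the melanosomal protein Mlana at -0.92 ± 0.09 and the receptor Kit at -0.89 ± 0.11. Of 17 p53 targets 11 rose and 1 fell (13 and 1 adjusted over the list alone; camera adjusted p = 5.7e-12), with Plk2 at 1.27 ± 0.10 and Eda2r at 1.23 ± 0.08. Of 22 interferon response genes 11 rose and 1 fell (19 and 1 adjusted over the list alone; camera adjusted p = 8.1e-10), with Oasl2 at 1.04 ± 0.15 and the RNA sensor Ddx58 at 1.03 ± 0.08. These 5 calls and that of the secreted factors (7 of 16 higher, 0 lower, 8 higher and 1 lower adjusted over the list alone, camera adjusted p = 4.3e-04) held with an estimated correlation.

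Single genes with the largest rises in the negative control were Ifi204 (2.17 ± 0.14), Dglucy (1.90 ± 0.09), the serotonin receptor Htr5b (1.69 ± 0.09), the integrin Itga7 (1.58 ± 0.09) and Ddias (1.57 ± 0.06). Ifi204 belongs to a family of closely related genes and was dim in the hypoxia control (3.90), so its value is uncertain. The largest falls were in the protease Bace2 (-1.39 ± 0.09), Atp6v0d2 (-1.36 ± 0.15), the transcription factor Irf4 (-1.36 ± 0.06) and Rab27a. In all 3396 genes passed the test, 1730 higher and 1666 lower, with 55 at least 2-fold higher and 11 at least 2-fold lower. The cholesterol synthesis (6 of 15 lower, 0 higher, 8 lower adjusted over the list alone) and respiratory chain lists (3 of 30 lower, 0 higher, 3 lower adjusted over the list alone) were called at camera adjusted p = 4.3e-04 and 0.013. Both calls were lost with an estimated correlation (adjusted p = 0.161 and 0.309). The glycolysis and hypoxia adaptation lists were not called (medians -0.06 and -0.03, camera adjusted p = 0.115 and 0.603).

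Under hypoxia, both Hif1a siRNAs lowered the genes that low oxygen had raised most. In the mean of Si1 and Si6 against the negative control, the largest falls were in Stc1 (-3.81 ± 0.08), Prelid2 (-3.78 ± 0.09), Bnip3 (-3.77 ± 0.06), Pdk1 (-3.0 ± 0.08), the proprotein convertase Pcsk6 (-2.78 ± 0.05), the HIF prolyl hydroxylase Egln3 (-2.74 ± 0.13), Plekha2 (-2.67 ± 0.07), Vldlr (-2.64 ± 0.08), the adenylate kinase Ak4 (-2.50 ± 0.05) and Spry3 (-2.49 ± 0.07). The largest rises were in Chac1, a glutathione-degrading enzyme (2.05 ± 0.07), the cystine transporter Slc7a11 (2.02 ± 0.06), the phosphate transporter Slc20a1 (1.80 ± 0.05), the ribonucleotide reductase subunit Rrm2 (1.73 ± 0.05), the folate enzymes Mthfd2 (1.7 ± 0.06) and Shmt2 (1.67 ± 0.06), the neutral amino acid transporter Slc1a4 (1.66 ± 0.08), and asparagine synthetase Asns (1.60 ± 0.06). Second probe sets of Pdk1 (-0.09), Plekha2 (-0.11), Slc7a11 (0) and Rrm2 (0.09), dimmer by the mean over all arrays, did not show these changes. Of the genes above the lowest limma adjusted p was 4.2e-15 for Bnip3, and that of Egln3, the least precise, was 5.0e-10. With Si1, 7750 genes passed the test, 4472 higher and 3278 lower. With Si6 there were 6400, 3770 higher and 2630 lower, and for the mean of both 7426, 4367 higher and 3059 lower. The share of higher genes for Si1, Si6 and their mean was 57.7%, 58.9% and 58.8% as deposited, 58.7%, 55.6% and 58.4% after quantile normalization, and 65.1%, 67.7% and 67.8% after median centring. At least 2-fold changes numbered 282 up and 237 down with Si1, and 63 up and 162 down with Si6.

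Every measured gene of the hypoxia adaptation list (25 of 25) fell with each siRNA, also adjusted over the list alone. Its median was -1.08 with Si1 and -0.85 with Si6 (camera adjusted p = 3.3e-23 and 1.7e-28). In the glycolysis list, 16 of 21 genes fell and 4 rose with Si1, and 15 fell and 1 rose with Si6, the same numbers adjusted over the list alone (camera adjusted p = 2.3e-09 and 9.2e-15). Pfkl, a subunit of the enzyme that commits glucose to glycolysis, was at -2.55 ± 0.08 with Si1 and -1.68 ± 0.08 with Si6, and Gys1 at -1.68 ± 0.06 and -1.60 ± 0.06. Of 13 JmjC demethylases 11 fell with Si1 and 9 with Si6, 0 rose (11 and 9 adjusted over the list alone; camera adjusted p = 1.9e-08 and 5.7e-08), and Kdm4b was at -1.56 ± 0.06 and -1.19 ± 0.06. These calls held with an estimated correlation. The secreted factors were called with Si6, 10 of 16 lower and 1 higher (11 and 1 adjusted over the list alone; camera adjusted p = 1.2e-07), and that call held too. With Si1 they were not called, with 7 lower and 4 higher (7 and 5 adjusted over the list alone), a median of 0.01, a mean of -0.51 and a downward test direction (camera adjusted p = 0.067). The difference between the siRNAs in this list was called (camera adjusted p = 0.01), a call lost with an estimated correlation (adjusted p = 0.104). The list of HIF subunits and regulators, which holds Hif1a itself, was called with Si1 (5 of 10 lower, 2 higher, the same adjusted over the list alone; camera adjusted p = 0.032), a call lost with an estimated correlation (adjusted p = 0.194). Epas1, which encodes the related HIF-2 alpha subunit, was at -0.76 ± 0.08 with Si1 and -0.34 ± 0.08 with Si6.

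Genes of biosynthesis, respiration and DNA replication were higher with both siRNAs. All 25 DNA replication genes rose with each siRNA (25 adjusted over the list alone), with medians of 0.70 and 0.66 and Rrm2 at 1.74 ± 0.06 with Si1 and 1.73 ± 0.06 with Si6 (camera adjusted p = 1.7e-16 and 8.1e-18). In the integrated stress response list 18 of 20 genes rose with Si1 and 19 with Si6, 0 fell (19 and 19 adjusted over the list alone; camera adjusted p = 1.8e-15 and 4.0e-18), with Asns at 1.66 ± 0.07 and 1.55 ± 0.07. Of 30 respiratory chain subunits 25 and 26 rose and 0 fell (25 and 29 adjusted over the list alone; camera adjusted p = 5.9e-11 and 5.7e-14), among them Cyc1 (0.95 ± 0.06 and 0.80 ± 0.06) and Sdhb (0.90 ± 0.06 and 0.73 ± 0.06). Of 14 citrate cycle genes 13 and 14 rose and 0 fell (13 and 14 adjusted over the list alone; camera adjusted p = 8.5e-09 and 1.5e-09), led by Idh3a at 1.39 ± 0.05 and 0.87 ± 0.05. Of 19 ribosome biogenesis genes 18 and 15 rose and 0 fell (18 and 16 adjusted over the list alone; camera adjusted p = 2.3e-13 and 2.4e-07), with Ddx21 at 1.11 ± 0.06 and 0.59 ± 0.06 (0.11 and 0.14 with a second, dimmer probe set, neither past the test). All of these calls held with an estimated correlation. Of 15 cholesterol synthesis genes 14 rose and 0 fell with Si1 and 10 rose and 1 fell with Si6 (14 and 0, 11 and 1 adjusted over the list alone; camera adjusted p = 1.2e-07 and 1.0e-04), and the Si6 call was lost with an estimated correlation (adjusted p = 0.078). Of 18 ER chaperone genes 12 and 11 rose and 3 and 3 fell (the same adjusted over the list alone; camera adjusted p = 0.001 and 0.003), and both calls were lost with an estimated correlation (adjusted p = 0.056 and 0.075).

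**Figure D2:**
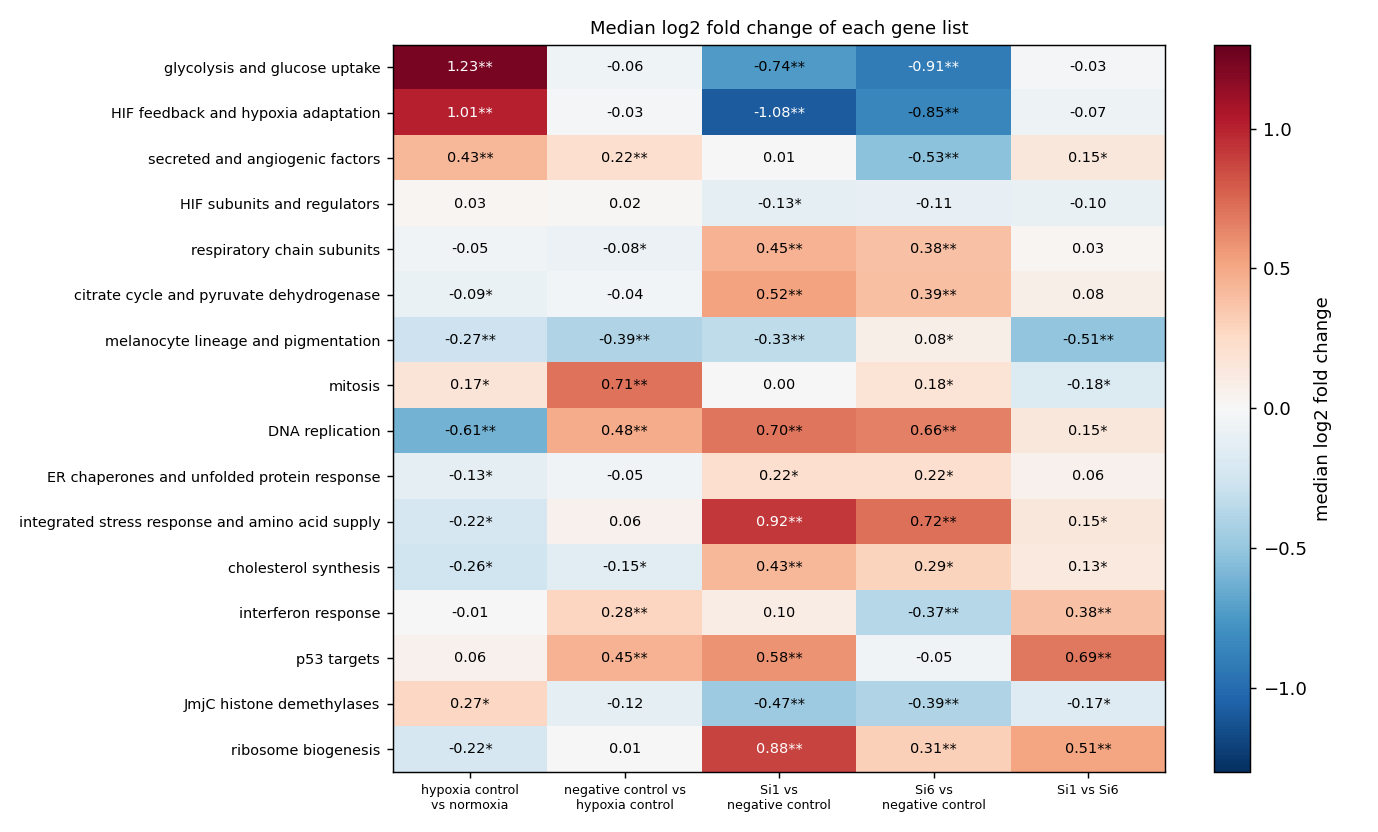
Median log2 fold change of the 16 fixed gene lists (rows) in 5 comparisons (columns), printed in each cell and coloured from blue (lower) to red (higher), with one star for a camera call with the preset correlation alone and a pair of stars where it also held with an estimated correlation. The glycolysis list goes from 1.23 with hypoxia to -0.74 and -0.91 with the siRNAs, and DNA replication from -0.61 to 0.70 and 0.66.

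Across genes, the siRNA changes ran against the hypoxia changes. The correlation of hypoxia fold changes with those of the siRNA mean was r = -0.52 and rho = -0.34 over 22180 genes, which are not independent replicates. These contrasts share no arrays, and simulated unchanged groups gave a mean r of 0. Of the 2190 genes raised by hypoxia, 761 were lower with both siRNAs, where independent lists would share 152.5, and 98 were higher with both (246.3 if independent). Of the 2474 genes lowered by hypoxia, 1080 were higher with both (278.2 if independent) and 99 lower with both (172.3). Among the 128 genes raised at least 2-fold, 108 fell with both siRNAs and 0 rose with both. By limma, 6 of the 128 rose with Si1 and 0 with Si6. Their median was 1.34 with hypoxia and -1.06 with the siRNA mean (camera p = 1.6e-67, or 5.4e-06 with an estimated correlation). Of the 30 genes lowered at least 2-fold, 13 rose with both and 4 fell with both. For those 30 the camera p for the siRNA mean was 3.8e-05, and the call was lost with an estimated correlation (p = 0.073).

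Genes raised by hypoxia and lower with both siRNAs included, besides those named, Hk2 (-1.63 ± 0.07 with Si1 and -1.55 ± 0.07 with Si6), Adm (-2.12 ± 0.11 and -2.19 ± 0.11), Higd1a (-1.72 ± 0.08 and -1.73 ± 0.08) and the glycogen branching enzyme Gbe1 (-2.64 ± 0.06 and -2.10 ± 0.06). In the opposite direction were Cpt1a (0.30 ± 0.05 and 0.90 ± 0.05), Mcm2 (1.18 ± 0.06 and 1.03 ± 0.06), the folate enzyme Mthfd1 (1.05 ± 0.08 and 0.71 ± 0.08), the chromatin remodeller Hells (1.02 ± 0.07 and 0.79 ± 0.07) and the glycosyltransferase Alg3 (1.06 ± 0.05 and 0.82 ± 0.05). A smaller set was raised by hypoxia and higher still with both siRNAs, among them the translation inhibitor Eif4ebp1 (0.61 ± 0.07 with hypoxia, then 0.58 ± 0.07 and 0.32 ± 0.07) and the nerve growth factor receptor Ngfr (0.44 ± 0.08, then 1.56 ± 0.08 and 1.26 ± 0.08). Lowered by hypoxia and lower again with both were Abca12 (-1.46 ± 0.08, then -1.27 ± 0.08 and -0.64 ± 0.08), the collagen gene Col1a1 (-1.0 ± 0.09, then -0.81 ± 0.09 and -0.36 ± 0.09) and the mitophagy kinase Pink1 (-0.57 ± 0.06, then -0.76 ± 0.06 and -0.30 ± 0.06).

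**Figure D3:**
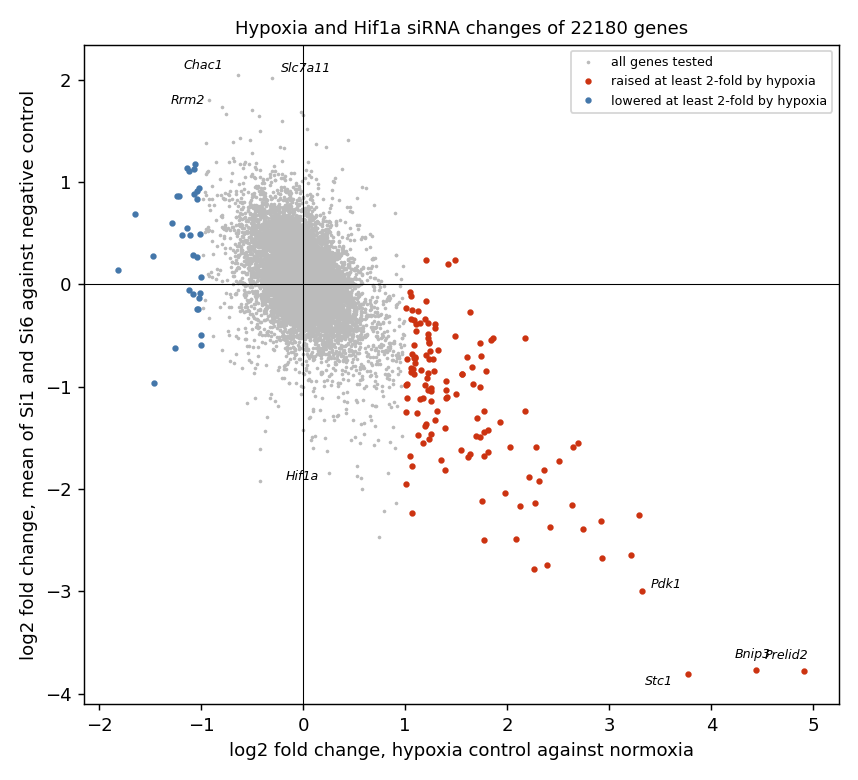
Each point is one of 22180 genes, with its log2 fold change in the hypoxia control against normoxia (horizontal) and in the mean of Si1 and Si6 against the negative control (vertical). Red points are the 128 genes raised at least 2-fold by hypoxia, of which 108 fell with both siRNAs, and blue points the 30 genes lowered at least 2-fold.

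The siRNAs also differed from each other, with Acta2, Plaur and Tnc among the genes higher in Si1 and most pigmentation genes lower. Smooth muscle actin Acta2 was at 11.41 ± 0.01 (SD, n = 3) in Si1 and 8.01 ± 0.05 in Si6, against 8.06 ± 0.08 in the negative control, a difference between siRNAs of 3.40 ± 0.08 (adjusted p = 6.2e-13). Wincr1 (3.46 ± 0.08), the urokinase receptor Plaur (3.21 ± 0.11), the protease inhibitor Serpinb2 (3.16 ± 0.14), the matrix protein tenascin C, Tnc (3.02 ± 0.08), Tmem171 (2.79 ± 0.10), the keratin Krt17 (2.78 ± 0.12), Lce1h (2.74 ± 0.15), Actg2 (2.58 ± 0.08) and the chemokine Ccl9 (2.31 ± 0.10) were the other largest rises in Si1 over Si6. The largest falls were in Ednrb (-2.20 ± 0.10), Ogn (-2.20 ± 0.07), the iron exporter Slc40a1 (-2.16 ± 0.08), Fbxw18 (-2.01 ± 0.12), Dynlt3 (-1.95 ± 0.11), Sgk3 (-1.80 ± 0.05), Adhfe1 (-1.78 ± 0.07), Vmn1r181 (-1.66 ± 0.16), Fbxw24 (-1.54 ± 0.14) and the connexin Gjb2 (-1.54 ± 0.08). Fbxw18, Fbxw24 and Vmn1r181 belong to families of near-identical genes and are uncertain. In all 6198 genes differed between the siRNAs, 3221 higher and 2977 lower in Si1, 189 and 91 of them at least 2-fold.

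Of 23 pigmentation genes 20 were lower in Si1 than in Si6 and 0 higher (20 and 1 adjusted over the list alone), with a median of -0.51 (camera adjusted p = 6.3e-14). Against the negative control the list was lower in Si1 (15 lower, 2 higher, the same adjusted over the list alone; camera adjusted p = 2.2e-06) and higher in Si6 (9 higher, 4 lower, 10 and 4 adjusted over the list alone; camera adjusted p = 0.034), and the Si6 call was lost with an estimated correlation (adjusted p = 0.315). The master regulator Mitf was at -0.93 ± 0.05 in Si1 against the negative control, and Kit at 1.11 ± 0.11 in Si6. Of 17 p53 targets 14 were higher and 2 lower in Si1 than in Si6 (14 and 2 adjusted over the list alone; camera adjusted p = 1.8e-08), with Plk2 at 1.54 ± 0.10 and Btg2 at 1.26 ± 0.08. Of 19 ribosome biogenesis genes 17 were higher and 0 lower (18 adjusted over the list alone; camera adjusted p = 1.5e-10), and of 22 interferon genes 15 were higher and 1 lower (16 and 1 adjusted over the list alone; camera adjusted p = 8.6e-07), with Usp18 at 1.55 ± 0.11. These 4 differences held with an estimated correlation. Against the negative control the p53 targets were called in Si1 (13 of 17 higher, 1 lower, 14 and 1 adjusted over the list alone; camera adjusted p = 4.1e-07) and not in Si6 (camera adjusted p = 0.62). The interferon genes were called in Si6 (16 of 22 lower, 1 higher, 18 and 1 adjusted over the list alone; camera adjusted p = 7.8e-06) and not in Si1 (camera adjusted p = 0.249). The mitosis list was called in Si6 (10 of 20 higher, 1 lower, 12 and 3 adjusted over the list alone; camera adjusted p = 0.01, and adjusted p = 0.41 with an estimated correlation) and not in Si1 (camera adjusted p = 0.268). Its difference between the siRNAs was called (camera adjusted p = 8.5e-05) and lost with an estimated correlation (adjusted p = 0.353).

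**Figure D4:**
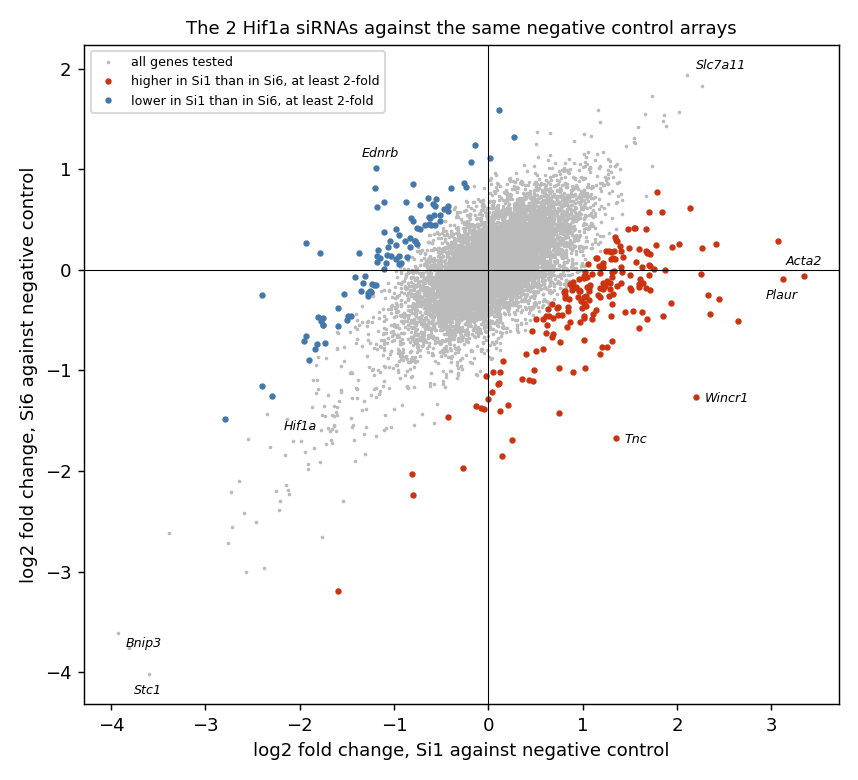
Each point is one of 22180 genes, with its log2 fold change against the negative control in Si1 (horizontal) and in Si6 (vertical). Red points are the 189 genes at least 2-fold higher in Si1 than in Si6, with Acta2 and Plaur farthest right, and blue points the 91 genes at least 2-fold lower, with Ednrb among them.

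Most genes that both siRNAs changed moved the same way. Of 4579 genes past the test with each siRNA, 4039 (88.2%) changed in the same direction, 2494 higher and 1545 lower, and 540 in opposite directions. Both contrasts use the same negative control arrays, which alone favours a shared sign. Over all genes 71.4% had the same sign with both siRNAs, against 66.7% for simulated unchanged groups. Independent lists would share 760.1 higher and 388.7 lower genes. Fold changes of the siRNAs correlated at r = 0.62 across genes, against 0.50 for simulated unchanged groups, and their covariance was 0.0639 against 0.0036, a difference of 0.0603. The 3 negative control arrays were not divided between the siRNAs, so part of the excess over independent lists may come from these shared controls.

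By median level, the marker lists of other cell types lay below the median gene, except the Schwann cell or glia list, at percentile 54.6. Levels of different probe sets are not directly comparable, so they do not show whether such cells were present. The median level was 6.22 log2 units for 8 fibroblast markers, 6.04 for 7 keratinocyte markers, 7.18 for 5 Schwann cell or glia markers, 6.09 for 7 macrophage or leukocyte markers and 5.8 for 6 endothelial markers. No marker list was called by camera in any comparison. The counts that follow hold only markers past limma's test as deposited and in every alternative run for them. With hypoxia 2 fibroblast markers fell (Col1a1 and Col1a2), 2 glial markers rose (Mbp and Ngfr) and 1 fell (Fabp7), and 1 macrophage marker rose (Cd68) and 1 fell (Lyz2). In the negative control against the hypoxia control, only Col1a1 was kept, and it was higher. Against the negative control, 3 glial markers were lower in Si1 (Mbp, Fabp7 and Mal) and 1 higher (Ngfr), as the pigmentation list was also lower there, Cd68 was higher and Col1a1 lower. In Si6, Mal, Ngfr and Col1a2 were higher and Mbp, Col1a1 and the keratinocyte marker Lamb3 lower. Between Si1 and Si6, Col1a1, Col1a2 and 3 glial markers were lower in Si1 (Fabp7 at -1.22 ± 0.07), and Lamb3, Cd68 (1.13 ± 0.08) and Cd14 (0.51 ± 0.11) higher. No endothelial marker passed limma's adjusted test in any comparison.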

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

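The tests of interferon genes, of fibroblast markers, of level-matched genes, with parted arrays, of distances from the normoxia level and of sums of siRNA and hypoxia changes were chosen after the results that prompted them had been seen. The 2 SE given with medians and shares in these tests are taken over genes, treated as independent, and hold no spread between arrays. They are too narrow where genes move together. The siRNA effects differed from each other in 6198 genes. Of the fixed gene lists, 10 differed between Si1 and Si6, with median log2 differences (Si1 minus Si6) of -0.51 for pigmentation, 0.69 for p53 targets, 0.51 for ribosome biogenesis and 0.38 for the interferon response, and these 4 held with an estimated correlation. The other 6 did not hold with one. They were mitosis (-0.18, estimated-correlation adjusted p = 0.353), JmjC demethylases (-0.17, 0.335), DNA replication (0.15, 0.384), the integrated stress response (0.15, 0.353), secreted factors (0.15, 0.104) and cholesterol synthesis (0.13, 0.335). Of the named genes, 13 passed the test in opposite directions with the siRNAs. Higher in Si1 were Wincr1 (difference 3.46), Serpinb2 (3.16), Tnc (3.02), Tmem171 (2.79), Actg2 (2.58) and Ccl9 (2.31), and lower were Ednrb (-2.20), Ogn (-2.20), Fbxw18 (-2.01), Sgk3 (-1.80), Adhfe1 (-1.78), Vmn1r181 (-1.66) and Fbxw24 (-1.54). Ednrb, for example, was at -1.19 in Si1 and 1.01 in Si6 against the negative control. Among 17824 probe sets without a single gene name, which enter no comparison above, 1807 passed the test between the hypoxia control and normoxia, 629 higher and 1178 lower.

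The first pattern is that 66 genes differed at least 2-fold between the negative control and the hypoxia control. Their changes were not shared by genes of like level. The 200 genes nearest in level to each of the 66 had a median log2 change between -0.06 and 0.02, in the gene's own direction at most 0.05 of its change. Normalization between arrays holds such medians near 0, and the 66 genes were chosen for large changes, so little else could have come out. Whether scaling contributed is therefore not decided, and a change of all genes together could not be seen. A rise of interferon genes was not seen in all of the negative control, Si1 and Si6. The interferon list's median against the hypoxia control was 0.28 ± 0.17 (2 SE of members) in the negative control and 0.43 ± 0.27 in Si1 but -0.02 ± 0.14 in Si6. In Si6, 16 of the 22 genes were lower than in the negative control and 1 higher. A response shared by the 3 groups and then lowered by Si6 would give the same values, so it stays open. The list also does not stand for the 66 genes. A condition shared by those 3 groups, or one particular to the hypoxia control, is a candidate source: 44 of the 66 genes changed the same way in both siRNA groups against the same hypoxia control arrays, and with separate hypoxia control arrays for choosing and testing the share was 0.62 to 0.67, where at least 0.5 was required and at most 0.19 of all genes did so. The labels do not say what the negative control received, so transfection itself was not separately tested, and the remaining genes stay open.

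For the second pattern, the 280 genes that differed at least 2-fold between Si1 and Si6, deeper Hif1a knockdown by Si1 is argued against as the whole cause, because of 173 of these genes that Si6 changed against the negative control, 136 changed opposite to the direction in which Si1 differed from Si6. Both contrasts use the Si6 arrays, which alone favours opposite signs, but with separate Si6 arrays for choosing and testing the share was still 0.75 to 0.83 (2 SE at most 0.07), against 0.5 without any effect. For the 144 genes without such an opposite change, further loss of the hypoxia response cannot be told apart from other causes, since 40 (a share of 0.28 ± 0.07, 2 SE) changed with hypoxia in the direction opposite to the siRNA difference, which goes with it, and 26 in the same direction, which goes against it. Fibroblasts in the Si1 cultures are argued against, as the median difference of 8 fibroblast markers was -0.02 ± 0.21 (2 SE of members) and of the collagen genes these cells make, Col1a1 and Col1a2 were lower in Si1 (-0.45 and -0.52, the latter 0.04 with a dimmer second probe set) and Col3a1 did not differ detectably (0, adjusted p = 0.987), although 3 of the 8 markers lay above the median gene on these arrays, Col1a1 brightest at 8.56. Effects of either siRNA on transcripts other than Hif1a were not tested here and stay open, as does any difference in how the cultures were handled.

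The third pattern is that 4 lists, DNA replication, respiratory chain, integrated stress response and ribosome biogenesis, rose with both siRNAs. The citrate cycle list, in which 13 of 14 genes rose with Si1 and 14 with Si6, was not put to the tests below. The 4 lists rose in excess of genes of like level. That median excess, over the 200 genes nearest in level to each member, was at least 0.38 ± 0.10 (2 SE of members), the value of the respiratory chain. The lists were chosen for their rise and normalization holds the matched genes near 0, so this excess does not decide whether scaling contributed. A shift of all genes together, which normalization hides, was not tested. For the respiratory chain and the integrated stress response, a mere loss of the hypoxia repression is argued against for both siRNAs, since their mean lay above normoxia by a median of 0.26 ± 0.10 and 0.73 ± 0.38, and the sum of siRNA and hypoxia changes, which leaves out the step from hypoxia control to negative control, was 0.33 ± 0.10 and 0.75 ± 0.28 (0.39 ± 0.12 and 0.81 ± 0.32 with Si1, 0.33 ± 0.09 and 0.72 ± 0.26 with Si6). By limma, 24 of 30 and 15 of 20 members were higher in that mean than in normoxia, and 2 and 1 lower. Hypoxia itself moved the respiratory chain little (median -0.05). The residuals of members correlated at an estimated 0.11 and 0.15, so these intervals, widest for the stress response, are too narrow. For ribosome biogenesis (0.42 ± 0.12 above normoxia in the siRNA mean), a mere loss of the hypoxia repression is argued against with Si1. There the list lay 0.6 ± 0.14 above normoxia and the sum was 0.67 ± 0.12. It stays open with Si6, at 0.25 ± 0.13 above normoxia and a sum of 0.12 ± 0.12. For DNA replication it stays open with both, because the list's 0.56 ± 0.10 above normoxia goes with a rise of 0.48 already in the negative control, and the sum was 0.02 ± 0.14. That Hif1a holds the respiratory chain and stress response lists down in hypoxia may be a hypothesis, untested in normoxic cells with these siRNAs, and CO2, transfection and effects that both siRNAs share apart from Hif1a remain open.

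For the 5 comparisons of 3 arrays against 3, the 10 possible splits are too few for a share under 0.05. In each, 1 split (the real one) gave as many genes, with 4664, 3396, 7750, 6400 and 6198 genes for hypoxia, the negative control, Si1, Si6 and Si1 against Si6, and 0 for the highest other split. For the mean of both siRNAs, treated as one group of 6 against the negative control, 1 of 84 splits gave as many genes as the real 5194, so a random division of the arrays is argued against as the source. The next highest, 4999 and 2497, set apart the 3 Si1 or the 3 Si6 arrays, which points to the groups themselves as structure, and the fourth gave 0. Of 100 splits of the negative control and siRNA arrays, 1 gave as many hypoxia-raised genes lower with both siRNAs (761, highest other 531) and 1 as many hypoxia-lowered genes higher with both (1080, highest other 669), the real one in each case. A random division of the arrays is argued against for both. The arrays split come from 3 groups that differ, so these splits do not show which difference between the groups matters.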

How the results depend on the processing

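Every count of changed genes stayed within 1.5 times its value in all settings run, and no call on them was lost. Leaving out each array in turn gave 3807 to 4448 genes for hypoxia, 2518 to 3053 for the negative control, 6948 to 7328 for Si1, 5503 to 5925 for Si6, 6580 to 7340 for their mean and 5322 to 5571 between the siRNAs. The replicate letters did not pair the arrays (3 of 30 same-letter pairs correlated above 0.1, range -0.22 to 0.21, and 5 of 15 arrays were closest to their own letter), and with the letter as a replicate block 4460 genes passed for hypoxia, 3137 for the negative control and 7263 for the siRNA mean. The correlation of hypoxia and siRNA changes moved from -0.52 to -0.55 and -0.57 without the lowest 25% and 50% of genes, and to -0.43 with the negative control in place of the hypoxia control, a choice that shares arrays between the contrasts. With the mean of all probe sets, which adds a dim Hif1a probe set that does not respond, the Hif1a change was 0.12 with hypoxia (adjusted p = 0.134) and -0.11 between the siRNAs (adjusted p = 0.173), both no longer past the test, and -0.02 for the negative control, reversed from 0.05 with neither past the test. The direction of 6 list tests turned, none called before or after, with medians of 0.044 for the integrated stress response in the negative control and 0.077 for mitosis in the siRNA mean (lowest 50% left out), 0.048 for mitosis in the siRNA mean (quantile normalization), and, for HIF subunits in the negative control, -0.003 (mean of all probe sets) and, leaving out each array in turn, -0.007 to 0.061 (0.003 without negative control replicate b). The cause of these was not tested. Of the other list results 44 lost and 22 gained a call, 23 of the losses with the estimated correlation. Of the named-gene values 206 lost and 10030 kept their side of the threshold, and 0 reversed. Only values past the test as deposited were followed, so none could gain a call. Many were named for the size of their change, which makes a reversal unlikely. Under the deposited values and both scalings the median gene's change lay between -0.016 and 0.028. Lists were not tested without variance moderation. The table has no background values, so changes of dim genes are limited by an unknown floor.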

Other observations

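The gene families below were chosen by symbol after the data had been seen, 13 in all, and tested with camera adjusted over the 13. Not all are described in detail. V-ATPase subunits were called with Si6 (10 of 21 higher, 1 lower, camera adjusted p = 0.001, or 0.026 with an estimated correlation). Collagens were called in the siRNA mean (14 of 44 lower, 2 higher, camera adjusted p = 2.4e-04). Kinesins were called in the negative control against the hypoxia control (14 of 37 higher, 1 lower, camera adjusted p = 1.3e-04). The collagen and kinesin calls were lost with an estimated correlation (adjusted p = 0.245 and 0.059). Of 53 cytosolic ribosomal proteins 9 rose and 1 fell in the siRNA mean against the negative control, with a median of 0.09 (camera adjusted p = 0.039, or 0.33 with an estimated correlation). With Si1 16 rose and 0 fell (camera adjusted p = 0.008, or 0.293 with an estimated correlation), with Si6 6 rose and 1 fell (not called, camera adjusted p = 0.351), and with hypoxia 22 rose and 0 fell (camera adjusted p = 9.8e-06, or 0.104 with an estimated correlation). Of 15 aminoacyl-tRNA synthetases 14 rose and 0 fell in the siRNA mean against the negative control, with a median of 0.63 (camera adjusted p = 2.9e-12, or 0.046 with an estimated correlation), led by Gars (1.34 ± 0.04) and Cars (1.16 ± 0.05). Members of this family such as Gars are also in the fixed stress response list. Of 38 proteasome subunits 26 rose and 2 fell, with a median of 0.30 (camera adjusted p = 4.1e-09, or 0.046 with an estimated correlation) and Psmc4 at 0.61 ± 0.05. Of 71 mitochondrial ribosomal proteins 53 rose and 2 fell, with a median of 0.35 and Mrpl42 at 1.03 ± 0.07. Its camera adjusted p was 4.7e-14, and the call was lost with an estimated correlation (adjusted p = 0.067). For Si1 alone the synthetase and proteasome calls were also lost with an estimated correlation (both adjusted p = 0.059), and for Si6 they held (0.026 and 0.034). After quantile normalization the medians of the synthetases, proteasome and mitochondrial ribosomal proteins in the siRNA mean were 0.58, 0.27 and 0.32, and after median centring 0.67, 0.34 and 0.39.

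Integrins, the receptors that attach cells to matrix, rose in hypoxia. Of 23 genes 10 rose and 1 fell, with a median of 0.15 (camera adjusted p = 3.0e-04, or 0.04 with an estimated correlation), Itga2 at 1.01 ± 0.07 and Itga9 at -0.90 ± 0.09. With Si6 10 fell and 1 rose (camera adjusted p = 6.1e-05, or 0.026 with an estimated correlation), and with Si1 the family was not called (9 lower, 4 higher, camera adjusted p = 0.103). The difference between the siRNAs was called (camera adjusted p = 0.003) and lost with an estimated correlation (adjusted p = 0.15). In the siRNA mean 11 fell and 3 rose (camera adjusted p = 0.002, and 0.063 with an estimated correlation), with Itga2 at -1.95 ± 0.06, Itga7 at -1.52 ± 0.08 and Itga5 at 0.98 ± 0.05. Of 46 mitochondrial solute carriers 18 fell and 3 rose in hypoxia (camera adjusted p = 6.2e-04, or 0.04 with an estimated correlation), among them Slc25a35 at -1.65 ± 0.07 and Slc25a16 at -0.66 ± 0.06. With Si6 18 carriers rose and 5 fell (camera adjusted p = 0.003, or 0.043 with an estimated correlation). With Si1 the carriers were not called (19 higher, 9 lower, camera adjusted p = 0.168). In the siRNA mean 20 rose and 7 fell (camera adjusted p = 0.031, and 0.119 with an estimated correlation). Slc25a33 was at -0.58 ± 0.05 in hypoxia and 1.18 ± 0.05 in the siRNA mean. After quantile normalization and median centring the hypoxia medians were 0.18 and 0.16 for integrins and -0.05 and -0.05 for the carriers. The integrin medians were -0.12 and -0.06 with Si6 (-0.10 as deposited), -0.10 and -0.10 in the siRNA mean (-0.14 as deposited), and 0 and 0 with Si1, where the deposited -0.04 was not kept.

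The negative control set directly against normoxia gave 6723 changed genes, 3230 higher and 3493 lower, more than the 4664 of the hypoxia control. Across genes, the change from hypoxia control to negative control correlated with the hypoxia change at r = 0.04, where simulated unchanged groups sharing the hypoxia control arrays gave -0.50. The covariance was 0.0018 against a simulated -0.0036, a difference of 0.0054. Ednrb fell in the hypoxia control and again in the negative control, from 10.58 ± 0.11 (SD, n = 3) in normoxia to 9.50 ± 0.14 and 8.26 ± 0.06.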
